A study of Ovis aries with 32 samples.

How the data were processed

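The series measured messenger RNA in 4 adipose depots of 8 sheep (Ovis aries) by 3′ end sequencing. This reads the tail end of each transcript, so that read counts were used without a length correction. Per the labels' protocols, libraries came from total RNA with an RNA integrity number of at least 7. The depots were visceral (mesenteric), subcutaneous (sternal), perirenal and epicardial fat. The sheep were 4 control females and 4 females exposed to excess testosterone before birth, each of which gave all 4 depots, so that every combination of depot and treatment held 4 libraries from 4 different animals. The sheep are named here by the animal numbers in the labels: 98, 131, 132 and 201 were controls, and 48, 185, 233 and 255 were testosterone sheep.

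The deposited table holds raw read counts per gene for 28524 genes and 32 libraries, not normalized. Per the submitters' processing notes, FastQC 0.11.5, MultiQC 0.9, Trimmomatic 0.36, STAR, featureCounts 1.6.1, R 3.6.3 and DESeq2 1.24.0 were used, with no role or order given. The genome build, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical gene copies, may be assigned to the wrong member of a pair. Every value in the count table was a whole number, and 6247 genes had no count in any library. Genes are named by the symbols in the table. Of these, 10441 are locus numbers without a symbol, and 1753 are transfer RNA genes, which held 0.0109% of all counts and stayed in the totals. Names of neighbouring genes were taken from a RefSeq gene table of the assembly ARS-UI_Ramb_v3.0, whose coordinates are not printed.

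Total counts per library ran from 784135 to 8267824. With a floor of 3 counts over the 4 control libraries of a depot, a gene with no count could lie at up to 0.113 CPM (counts scaled to library size, as edgeR computes them) in visceral, 0.167 in subcutaneous, 0.116 in perirenal and 0.157 in epicardial fat. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Folds against a depot at 0 are given as lower bounds from this floor, with the other depot taken as the CPM of its 4 control libraries pooled. This pooled CPM can differ from the printed mean of the libraries. All 48 pairs of replicate libraries were compared: 0 held identical values, and the lowest chi-square per degree of freedom of their counts was 11.6, well above sampling noise, so each library counted as 1 replicate.

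From the counts, CPM were computed with edgeR 4.0.16 in R 4.3.3 on library sizes scaled by TMM factors, which lay between 0.882 and 1.11. Levels are printed as mean ± SD of these CPM with n = 4. Differences are log2 fold changes from edgeR's quasi-likelihood test (robust fit, genes kept by filterByExpr with a minimum count of 10, Benjamini-Hochberg adjustment over the genes tested, false discovery rate, FDR, under 0.05). Since that test gives no standard error (SE), the SE was computed as the size of the log2 fold change divided by the square root of the test's F statistic. Every adjusted p of a single gene printed here comes from that test unless another tool is named. The effect of testosterone was fitted within the 8 libraries of each depot, and once over depots on counts summed over the 4 depots of each sheep. Depot genes were fitted as 1 depot minus the mean of the other 3, separately in control and testosterone sheep, with the sheep as a block. Higher in a depot therefore means above that mean, and such a gene need not be highest there. The interaction was fitted on all 32 libraries with the sheep as a block, as a joint test of the 3 depot-by-treatment terms and as the effect in 1 depot minus the mean effect in the other 3.

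The block rests on the series design, in which the 4 depots came from the same animals. As a check, the deviations of each library from its group mean were correlated between depots: 41 of 48 correlations within 1 sheep were over 0.1, their mean was 0.230 (from -0.118 to 0.481), and the mean between different sheep was -0.0762. The last value is no separate comparison, since deviations from a group mean make it negative by construction when the first is positive. In each pair of depots 4 of 4 control sheep correlated best with themselves, and 2 to 4 of 4 testosterone sheep did.

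A set of 44 lists of genes, 26 of pathways and functions and 18 of cell types, was tested as groups with camera (limma 3.58.1, correlation preset at 0.01, and again with the correlation estimated per list) and with fry. Beside the members passing over all genes, the count adjusted over the list alone is given. A list with fewer than 3 measured members was not tested, and the list of mitochondrially encoded genes was void because 0 of its 26 symbols were in the table.

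Genes are named by a rule. For testosterone effects, up to 8 genes higher and 8 lower at FDR under 0.05 whose groups did not overlap were to be named. Where fewer than 5 genes passed, the 10 genes with a symbol and the smallest p were given as values that did not pass. From each list the 2 measured members with the smallest p could serve as examples, and ESR1, PPARG, ADIPOQ, LEP and UCP1 were among the genes that could be named anywhere. For the interaction the 10 genes with the smallest p, and for depot genes the 8 higher and 4 lower genes with the smallest p and a log2 fold change of at least 1 in size, were named. Genes passing the tests between treatments or the interaction tests, by edgeR over all genes, are named in full where they number 5 or fewer. Genes named outside this rule (LOC105603774, ARGLU1, LUC7L3, the control levels of further positional genes and the genes compared within single libraries) were chosen after their values were seen. The groups, tests, lists, naming rule and a set of alternatives were fixed before the data were examined.

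Alternatives were DESeq2 1.42.0 size factors and tests, no filter and a stricter filter on low counts (10 counts in at least 4 libraries), limma-voom with quality weights, limma-voom with the sheep as a random effect, 1 surrogate variable (sva 3.50.0), 1 fit of all libraries, an FDR of 0.10, fits with no sheep block, and leaving out each sheep in turn. Added after the data had been seen were fits without 2 libraries rich in ARGLU1 transcripts, without 1 mixed-looking epicardial library, without all 3, and fits with ARGLU1 or cardiac marker levels as covariate. Each count was also compared with the 35 splits of the 8 sheep into 4 and 4, or with 100 permutations of the depot labels within sheep.

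The procedure was tested on simulated counts with the overall mean and fitted spread of each gene and the real library sizes. Each gene had 1 mean in all libraries apart from the simulated change, so differences between sheep and depots were not simulated. In the fits of testosterone effects within 1 depot, 10% of simulated 2-fold changes and 74% of 4-fold changes were recovered in visceral fat, 12% and 76% in subcutaneous, 29% and 81% in perirenal, and 24% and 74% in epicardial fat. The recovery was 25% and 90% over depots, 16% and 76% for the visceral interaction, 72% and 93% for epicardial genes in control sheep, and 38% and 87% for epicardial genes in testosterone sheep. Unchanged genes also passed: 1 in visceral, 8 in subcutaneous, 8 in perirenal and 6 in epicardial fat, and 4 over depots. There were 6 for the visceral interaction, 10 for epicardial genes in control and 5 in testosterone sheep. Of 10 simulated lists raised 2-fold in the visceral testosterone comparison, 10 were recovered, and 0 of 190 unchanged lists passed. Genes were simulated as independent of each other and lists were filled at random. The 0 of 190 therefore says nothing about false calls for real lists, whose members can vary together.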

Results

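Gene expression was measured in 4 fat depots of female sheep, a large-animal model of polycystic ovary syndrome in which excess testosterone before birth leads to a metabolic and reproductive disorder in the adult. Mothers of the testosterone group received 100 mg (1.2 mg/kg) testosterone propionate in 2 ml corn oil 2 times a week from day 30 to day 90 of gestation. The adult daughters were ovariectomized and given a steroid replacement of 2 progesterone implants for 14 days followed by 4 estradiol implants of 30 mm for 18 h before tissue was taken. Visceral (mesenteric), subcutaneous (sternal), perirenal and epicardial fat of 4 control and 4 testosterone sheep gave 32 libraries. Total counts were 6093513 to 7980969 in visceral control, 2609183 to 8207718 in visceral testosterone, 3519829 to 5354843 in subcutaneous control and 784135 to 6538042 in subcutaneous testosterone libraries. They were 5048842 to 8267824 in perirenal control, 4242625 to 8085558 in perirenal testosterone, 2907037 to 5475892 in epicardial control and 1753228 to 5127310 in epicardial testosterone libraries. The first 3 principal components of all libraries held 24.7%, 15.9% and 7.20% of the variance.

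Some libraries stood apart from others of their group in ways the groups do not explain. ARGLU1, whose transcript keeps introns and is rich in the nucleus, reached 24926 CPM in the subcutaneous library of testosterone sheep 48 (1471 to 2391 in the other 3) and 17369 CPM in the visceral library of testosterone sheep 255 (587 to 1806). The splicing gene LUC7L3 was at 9942 and 8964 CPM in these libraries. In epicardial fat, transcripts of a list of cardiac muscle genes summed to 25348, 4969, 148 and 842 CPM in control sheep 98, 131, 132 and 201. They summed to 32815, 600, 4980 and 135 CPM in testosterone sheep 48, 185, 233 and 255, against 41 to 199 CPM in libraries of the other depots. The epicardial library of testosterone sheep 255 also carried HOXC6, a gene of trunk position, at 95.5 CPM, where the other 7 epicardial libraries held at most 2.17 CPM.

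**Figure D1:**
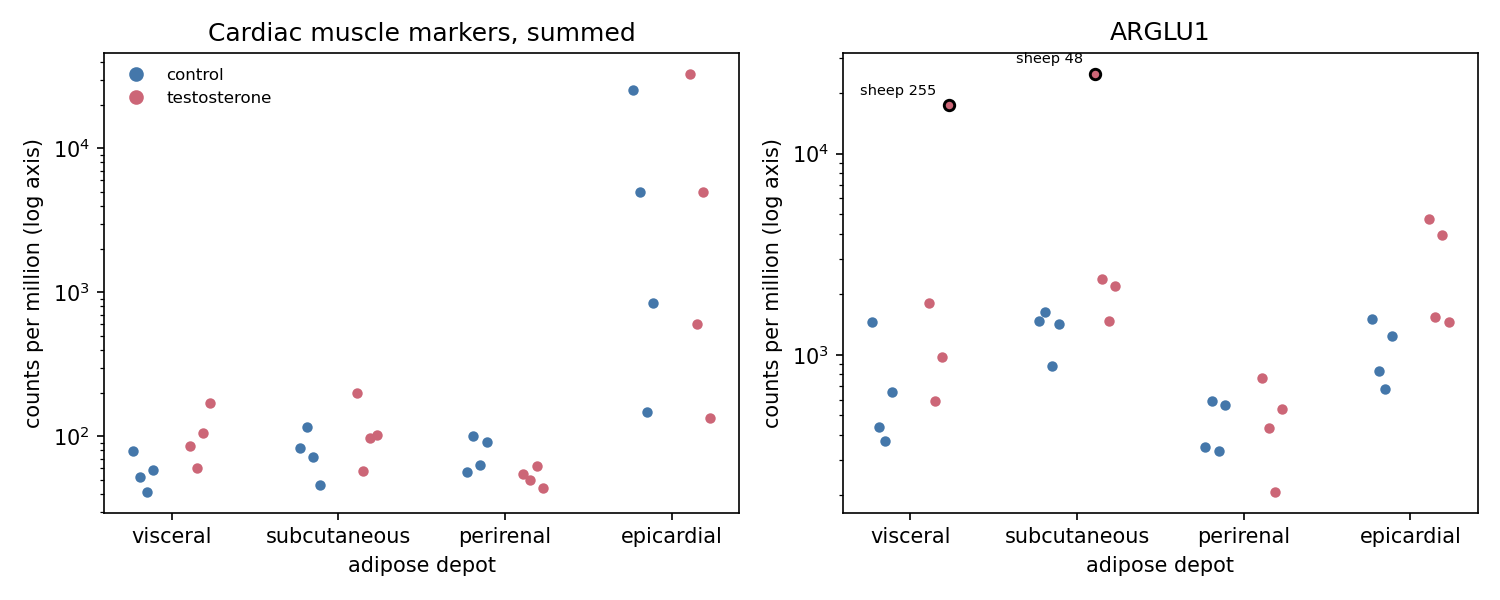
Summed CPM of the cardiac muscle genes (left) and CPM of ARGLU1 (right), both on log axes, with 1 point per library, by depot and treatment. Heart muscle transcripts spread from 135 to 32815 CPM in epicardial libraries, and the 2 outlined libraries, of testosterone sheep 48 and 255, hold ARGLU1 at 24926 and 17369 CPM.

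The first comparison asks which genes set each depot apart in control sheep. Subcutaneous fat was marked by genes of body position. The Iroquois genes IRX1 and IRX2 were at 28.0 ± 7.33 and 40.4 ± 9.66 CPM (SD, n = 4), and IRX1 had no count in visceral fat, where it was at least 244-fold lower than in subcutaneous fat (floor of 3 counts over the group). HOXC8 stood at 75.2 ± 10.4 CPM and had no count in any control epicardial library, so it was at least 479-fold higher in subcutaneous than in epicardial fat. It was not particular to subcutaneous fat: single control libraries held 66.5 to 87.6 CPM there and 57.4 to 92.8 CPM in perirenal fat. The mesodermal regulator TCF21 had no count in subcutaneous fat and 80.3 ± 16.1 CPM in epicardial fat, a difference of at least 496-fold from the pooled 83.0 CPM. The mesothelial gene WT1 was at 1.36 ± 1.06 CPM against 62.3 to 110 CPM in the other depots. In edgeR's test of subcutaneous fat against the mean of the other 3 depots, 3075 of 13369 genes passed, 1524 higher and 1551 lower.

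Among subcutaneous genes, the log2 fold change was 6.93 (SE 0.18, edgeR adjusted p = 2.91e-14) for IRX2, 3.34 (SE 0.15) for HOXC6, 1.87 (SE 0.10) for the zinc finger homeobox gene ZFHX4, -3.68 (SE 0.25) for the guidance factor SLIT2, and -3.06 (SE 0.21) for TMEM132C. HOXC9, HOXA9 and TBX15 stood at 67.4 ± 14.5, 46.1 ± 15.3 and 23.4 ± 13.0 CPM in subcutaneous fat, against 0.0431, 0.409 and 8.45 CPM in epicardial fat. In control perirenal libraries HOXC9 was at 81.55 to 129.8 CPM, HOXA9 at 30.8 to 50.58 CPM and TBX15 at no more than 0.1503 CPM. Of 36 homeobox and positional genes, 23 were higher and 4 lower (25 and 5 adjusted over the list alone; camera adjusted p = 1.65e-29, and adjusted p = 0.0132 with an estimated correlation). Of 10 T and NK cell genes, 10 were lower, among them CD3G at -2.28 and NKG7 at -1.72 (10 adjusted over the list alone; camera adjusted p = 5.23e-10, and adjusted p = 0.101 with an estimated correlation). Of 11 macrophage genes, 6 were lower, with TYROBP at -1.38 (8 adjusted over the list alone; adjusted p = 0.00299, and adjusted p = 0.519 with an estimated correlation). Of 5 mesothelial genes 3 were lower (4 adjusted over the list alone), including KRT19 at -3.06, and this list passed with both correlations (adjusted p = 2.13e-05, and adjusted p = 0.0175 with an estimated correlation).

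The clock list tested as higher in subcutaneous fat, with 4 of 14 members passing, among them PER1 at 1.22 (SE 0.15) and TEF at 1.12 (SE 0.18) (4 adjusted over the list alone; camera adjusted p = 0.0122, and adjusted p = 0.367 with an estimated correlation). Of 11 adipogenic transcription factors 4 were higher, such as KLF9 at 0.75, and 1, EBF2 at -0.80, was lower (7 and 1 adjusted over the list alone; adjusted p = 0.0382, and adjusted p = 0.357 with an estimated correlation). 2 lists of energy metabolism tested as lower, with 9 of 27 members passing for oxidative phosphorylation (11 adjusted over the list alone), such as NDUFA1 at -0.74, and 6 of 19 for fatty acid oxidation (8 adjusted over the list alone), such as DECR1 at -0.97. Their adjusted p were 2.76e-04 and 0.0116, and adjusted p = 0.646 and 0.357 with an estimated correlation. Ribosomal proteins, a list kept for library quality, were lower in 24 of 41 members, with RPL10 at -0.71 (1 higher and 32 lower adjusted over the list alone; adjusted p = 5.57e-09, and adjusted p = 0.497 with an estimated correlation). Lower lists also included heat shock proteins (7 of 15, HSPA4L at -1.89; 7 adjusted over the list alone) and imprinted genes (5 lower and 1 higher of 12, PEG3 at -1.38; 5 and 1 adjusted over the list alone). Their adjusted p were 0.00118 and 0.0223, and adjusted p = 0.357 and 0.249 with an estimated correlation.

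A further 4 cell or response lists tested as lower in subcutaneous fat, each by camera with the preset correlation only: interferon response (5 of 17, IFI44 at -0.81), smooth muscle (5 of 12, ACTA2 at -1.08), Schwann cell and neuron (5 lower and 1 higher of 10, CDH19 at -2.75) and neutrophil and mast cell (2 of 4, S100A8 at -2.57). Adjusted over the list alone, 5, 5, 7 and 3 members were lower. Their adjusted p were 0.00964, 0.0206, 0.00753 and 0.0337, and adjusted p = 0.539, 0.547, 0.411 and 0.367 with an estimated correlation. Leaving out 1 control sheep ended the calls of adipogenic factors (adjusted p = 0.154 without 201), the clock (0.0601 without 132), interferon response (0.125 without 132), neutrophils (0.0836 without 132) and smooth muscle (0.0590 without 98), and kept the other 10 lists. Over the 4 fits the gene count fell to between 1743 and 2286, at its lowest without sheep 132.

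Perirenal fat of control sheep held trunk HOX genes. It had HOXC6 at 218 ± 13.7 CPM, HOXC9 at 103 ± 21.0, HOXA9 at 43.6 ± 9.04 and HOXA10 at 23.0 ± 7.00 CPM, against 0.416, 0.0431, 0.409 and 0.0945 CPM in epicardial fat. In visceral fat, the other abdominal depot, these 4 genes were at 96.4, 6.02, 0.101 and 0.0694 CPM, and in subcutaneous fat at 211, 67.4, 46.1 and 7.64 CPM. The kidney stroma gene FOXD1 stood at 21.1 ± 3.53 CPM and at most 3.14 CPM elsewhere, while TBX15 and HAND2, at 0.0376 and 0.150 CPM, were near 0. By edgeR, 1841 of 13369 genes passed, 1034 higher and 807 lower.

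The perirenal log2 fold change was 4.35 (SE 0.30, edgeR adjusted p = 4.11e-08) for FOXD1, 3.38 (SE 0.15) for HOXC6, 3.10 (SE 0.20) for DMRT2, 2.00 (SE 0.13) for HOXD8, -1.29 (SE 0.15) for adenosine deaminase (ADA) and -1.87 (SE 0.22) for the matricellular gene CCN5. Of 36 positional genes 15 were higher and 2 lower (16 and 3 adjusted over the list alone; camera adjusted p = 1.30e-30, and adjusted p = 0.0110 with an estimated correlation). Ribosomal proteins were higher in 36 of 41 members, with RPL10 at 0.90 and RPS23 at 0.98 (38 adjusted over the list alone; adjusted p = 1.85e-25, and adjusted p = 0.345 with an estimated correlation). Of 5 mesothelial genes 2, WT1 at 1.87 and ALDH1A2 at 1.27, were higher (2 adjusted over the list alone; adjusted p = 0.00873, and adjusted p = 0.152 with an estimated correlation). Smooth muscle genes were higher in 5 of 12 members and lower in 1, with ACTG2 at 2.02 and ACTA2 at 1.11 (5 and 1 adjusted over the list alone; adjusted p = 0.00873, and adjusted p = 0.630 with an estimated correlation). Fatty acid oxidation (3 higher and 1 lower of 19, EHHADH at 0.88) and lymphatic endothelium (1 of 7, FLT4 at 1.33) also passed. Their adjusted p were 0.0440 and 0.0325, and adjusted p = 0.603 and 0.633 with an estimated correlation. Adjusted over the list alone, these counts were 4 and 1, and 3. The last 3 lists lost their calls without 1 sheep, at adjusted p = 0.117 without 131 for smooth muscle, 0.133 without 131 for fatty acid oxidation and 0.190 without 98 for lymphatic endothelium. The gene count fell to 656 without sheep 98, whose perirenal library had a fitted visceral share of 34.8%, 874 without 131 and 855 without 201, and was 1054 in the fit with no sheep block.

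Visceral fat of control sheep had the fewest genes of its own, among them ALDH1A1 and TF. ALDH1A1, a retinal dehydrogenase, was at 1607 ± 371 CPM against 346 to 706 CPM elsewhere, and transferrin (TF) at 104 ± 29.9 CPM against 18.7 to 72.0 CPM. SLIT2 was at 57.4 ± 10.1 CPM and HOXB5 at 12.2 ± 1.56 CPM, while HOXA9 and HOXA10 were near 0, at 0.101 and 0.0694 CPM. By edgeR, 766 of 13369 genes passed, 466 higher and 300 lower.

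The visceral log2 fold change was 3.59 (SE 0.20, edgeR adjusted p = 1.14e-08) for DMRT2, 2.20 (SE 0.17) for SLIT2, 1.65 (SE 0.13) for ALDH1A1, 1.52 (SE 0.13) for TF, 1.62 (SE 0.16) for the epoxide hydrolase EPHX2, 2.15 (SE 0.22) for PAMR1. It was -1.04 (SE 0.13) for the laminin LAMA2 and -1.77 (SE 0.24) for aminopeptidase A (ENPEP). DMRT2 was not particular to visceral fat: single control libraries held 133.2 to 168.4 CPM there and 94.81 to 164.6 CPM in perirenal fat. HOXC6 also passed as higher (1.81), though single control libraries held less of it in visceral fat (93.96 to 97.69 CPM) than in subcutaneous (193.1 to 225.1) or perirenal fat (199 to 228.5). The mean it was set against included epicardial fat, with at most 0.9311 CPM. Positional genes moved both ways: 12 of 36 were higher and 9 lower (15 and 10 adjusted over the list alone), and the list tested as higher with a median of 0.14 but a mean of -0.47 (camera adjusted p = 0.0220, and adjusted p = 0.568 with an estimated correlation). The angiogenesis and hypoxia list tested as higher, with 3 of 21 members passing, among them FLT1 at 0.69 and NDRG1 at 0.59 (9 adjusted over the list alone; adjusted p = 0.00624, and adjusted p = 0.143 with an estimated correlation). The macrophage list tested as higher (2 of 11 passing, CD68 at 0.97 and TYROBP at 0.81; 3 adjusted over the list alone), as did the mesothelial list (1 of 5, WT1 at 2.56; 1 adjusted over the list alone). Their adjusted p were 0.00236 and 0.0399, and adjusted p = 0.568 and 0.433 with an estimated correlation. The lists of heat shock proteins (4 of 15 passing, HSPH1 at 0.58), antioxidant genes (2 of 21, CAT at 0.69) and T and NK cells (0 of 10) tested as higher. Adjusted over the list alone, 4, 5 and 0 members passed. These 3 lists had adjusted p of 0.0279, 0.0486 and 0.0486, and adjusted p = 0.568, 0.568 and 0.578 with an estimated correlation. The lists of clock genes (2 of 14 passing, TEF at -0.87) and immediate early genes, which respond to tissue handling (2 of 20, JUNB at -0.58), tested as lower (7 and 2 adjusted over the list alone). Their adjusted p were 0.0394 and 0.0203, and adjusted p = 0.568 for both with an estimated correlation. Of these 9 lists, 1, angiogenesis and hypoxia, passed in all 4 fits without 1 sheep, and without sheep 131 it was the only one. The gene count was 202 without sheep 131, 269 without 201, 418 without 98 and 461 without 132, and 273 in the fit with no sheep block.

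Epicardial fat was the depot with the most genes passing against the mean of the other 3. Trunk HOX genes were almost absent: HOXC6 was at 0.416 ± 0.386 CPM and HOXB7 at 1.32 ± 0.426 CPM, against 96.4 to 218 and 27.5 to 40.8 CPM in the other depots. The imprinted preadipocyte factor DLK1 was at 256 ± 141 CPM (120.5 to 409.7 in single libraries) and had no count in subcutaneous fat. From its pooled 273 CPM the difference was at least 1630-fold. SOX9, a regulator of cartilage and heart valve progenitors, stood at 66.6 ± 12 CPM against 4.40 to 6.91 CPM, and angiotensinogen (AGT) at 28.7 ± 11.9 against 2.45 to 3.45 CPM. By edgeR, 3713 of 13369 genes passed, 2050 higher and 1663 lower. These libraries held the heart muscle transcripts described above. Of 5 measured cardiac muscle genes 5 were higher, with ANKRD1 at 7.90 (SE 0.83) and CASQ2 at 181 ± 290 CPM, an SD above its mean (5 adjusted over the list alone; camera adjusted p = 6.63e-04, and adjusted p = 0.282 with an estimated correlation).

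Other epicardial log2 fold changes were 3.76 (SE 0.18, edgeR adjusted p = 2.63e-10) for SOX9, 5.59 (SE 0.31) for the insulin receptor adaptor GRB14, 3.36 (SE 0.20) for AGT, 3.23 (SE 0.21) for SMTNL2, 2.50 (SE 0.16) for FSBP and 1.93 (SE 0.13) for the protease inhibitor TFPI2. HOXB7 was at -4.60 (SE 0.21). The neurofilament gene NEFL was at 18.9 ± 18.3 CPM and at most 0.202 CPM elsewhere. Of 36 positional genes 21 were lower and 12 higher (21 and 12 adjusted over the list alone; camera adjusted p = 1.45e-11, and adjusted p = 0.177 with an estimated correlation). Schwann cell and neuron genes were higher in 9 of 10 members, with CDH19 at 3.34, and lower in 1 (9 and 1 adjusted over the list alone; adjusted p = 5.12e-09, and adjusted p = 0.177 with an estimated correlation). T and NK cell genes were higher in 9 of 10 members, with IL7R at 1.36 and NKG7 at 1.30 (9 adjusted over the list alone; adjusted p = 0.00100, and adjusted p = 0.295 with an estimated correlation). Immediate early genes were higher in 10 of 20 members, with EGR3 at 2.32 and JUNB at 1.14, and lower in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.00326, and adjusted p = 0.282 with an estimated correlation).

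Angiogenesis and hypoxia genes were lower in 12 of 21 members in epicardial fat, with BNIP3 at -1.66 and NDRG1 at -1.55, and higher in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 6.24e-04, and adjusted p = 0.0936 with an estimated correlation). Endothelial genes were lower in 7 of 15 members, with CDH5 at -0.44 (9 lower and 2 higher adjusted over the list alone), antioxidant genes in 7 of 21, with catalase (CAT) at -1.73, and insulin signalling genes in 8 of 22, with GRB10 at -1.15. In the last 2 lists 1 and 2 members were higher, and the counts were the same adjusted over the list alone. These 3 lists had adjusted p of 0.0411, 0.0450 and 0.0395, and adjusted p = 0.282, 0.282 and 0.349 with an estimated correlation. Fibroblast genes were higher in 8 of 18 members, with COL3A1 at 1.39 and PDGFRA at 0.93, and lower in 2 (9 and 4 adjusted over the list alone; adjusted p = 0.0395, and adjusted p = 0.587 with an estimated correlation). Oxidative phosphorylation genes were higher in 10 of 27 members, with NDUFS1 at 0.97 (14 adjusted over the list alone; adjusted p = 0.00637, and adjusted p = 0.768 with an estimated correlation). That call was lost without sheep 98 (adjusted p = 0.483), the control with the most heart muscle transcripts. The antioxidant (0.111), fibroblast (0.119) and insulin (0.0774) calls were lost without sheep 132, and the endothelial call without 131 (0.0751).

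**Figure D2:**
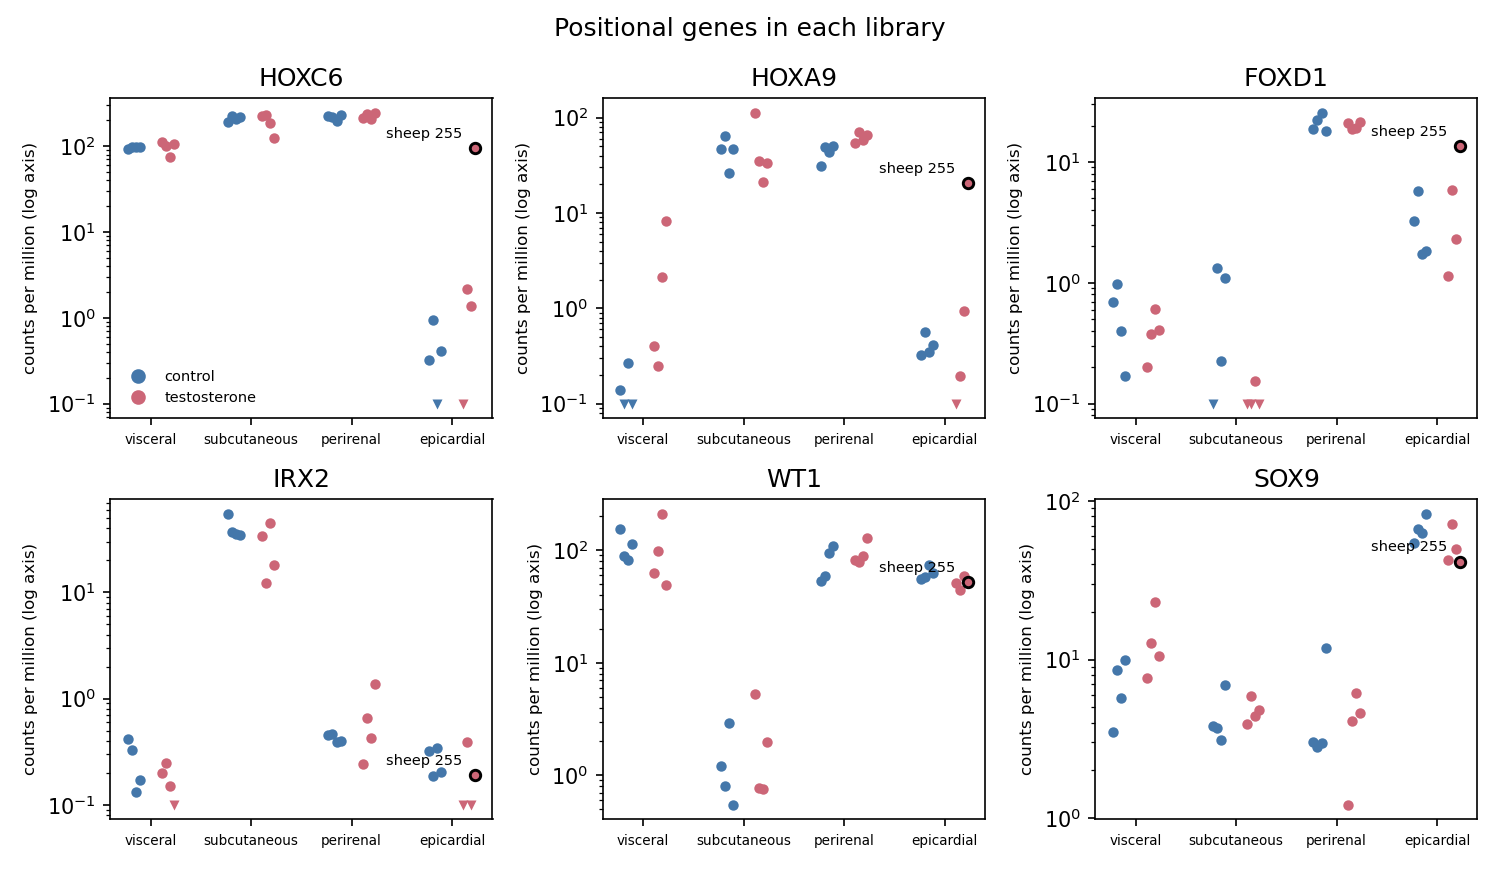
CPM of 6 positional genes on log axes, with 1 point per library, by depot and treatment; triangles mark libraries under 0.1 CPM, drawn at 0.1. HOXC6 stays at or below 2.17 CPM in 7 epicardial libraries and reaches 95.5 CPM in the outlined library of testosterone sheep 255, IRX2 marks subcutaneous fat (40.4 ± 9.66 CPM in controls), and SOX9 marks epicardial fat (66.6 ± 12 CPM in controls).

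The same depot comparisons were made in the testosterone sheep. The depot genes of the controls were largely seen again: IRX2 had a subcutaneous log2 fold change of 6.27, FOXD1 a perirenal one of 5.18, SLIT2 a visceral one of 2.32 and SOX9 an epicardial one of 3.10. Genes called in controls had the same sign in testosterone sheep in 83.3% of 753 visceral, 96.1% of 3033 subcutaneous, 94.1% of 1816 perirenal and 95.3% of 3638 epicardial genes. Without the 2 ARGLU1-rich libraries these shares were 94.0%, 93.9%, 93.9% and 95.9%. With all libraries, fewer genes passed edgeR's test than in controls, at 12 in visceral (9 higher, 3 lower), 341 in subcutaneous (167 and 174), 75 in perirenal (61 and 14) and 598 in epicardial fat (398 and 200), of 13411 tested. The 12 visceral genes were the stomach and spleen homeobox gene BARX1, SLIT2, EYA1, KRT23, PTGIR, ELMOD1, WT1, PAMR1, CFB, NRN1, CCL26 and the unnamed locus LOC101122940.

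Genes called in both groups of sheep numbered 10, 285, 51 and 511 in the same order of depots, against 0.690, 77.1, 9.99 and 161 expected of independent lists, and had the same sign in both but for 1 of the 51 perirenal genes. Among genes at odds, the smooth muscle genes ACTA2 and ACTG2, with perirenal log2 fold changes of 1.11 and 2.02 in controls, had values of -0.76 and -0.66 in testosterone sheep. HOXC6 was at -8.53 in control and -3.65 in testosterone epicardial fat, and DMRT2 at -8.15 and -2.66, where the library of sheep 255 carried both genes. Without the 2 ARGLU1-rich libraries and that epicardial library, 67 visceral, 400 subcutaneous, 825 perirenal and 2651 epicardial genes passed. No test compared the number of genes between the 2 groups of sheep, and without sheep 233 the counts were 3, 80, 8 and 101.

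**Figure D3:**
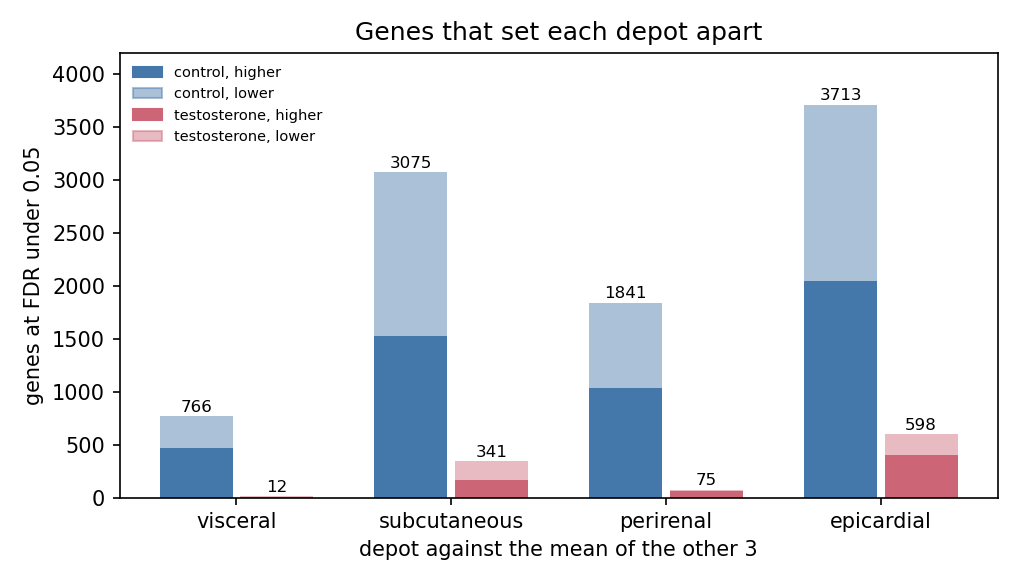
Number of genes at FDR under 0.05 in edgeR's test of each depot against the mean of the other 3, with the darker part of each bar for genes higher and the lighter part for genes lower in the depot, for 4 control and 4 testosterone sheep. Epicardial fat had the most genes in both groups, 3713 in control and 598 in testosterone sheep, and visceral fat the fewest, 766 and 12.

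The next comparison asks which genes differed between testosterone and control sheep within each depot. In visceral fat no gene passed edgeR's test. The genes with the smallest p, none of which overlapped between groups, were the Wnt receptor FZD8 at -1.03 (SE 0.20), the ankyrin repeat gene ANKEF1 at -1.60 (SE 0.32), the kinase MAPK7 at -1.49, the transcription factor MAFF at -1.39, and THNSL2 at -1.78. Next came the urokinase receptor PLAUR at -1.66, the ephrin receptor EPHA4 at 1.4, FAM241A at -1.35, RGCC at -1.39 and SNRPG at -1.36, and all 10 had an edgeR adjusted p of 0.521. The adipokine gene ADIPOQ was at -0.67 (SE 0.30), ESR1 at 0.47, LEP at 0.59 and PPARG at -0.23. By edgeR 0 of 12860 genes passed, 1212 had an unadjusted p under 0.05 (5% of the genes tested is 643), and DESeq2 called 21. The oxidative phosphorylation list tested as lower: 23 of 27 members were negative, with a median of -0.23, NDUFA1 at -0.69 and ATP5PF at -0.48. In this list 0 members passed (0 adjusted over the list alone), and camera gave adjusted p = 0.0224, and adjusted p = 0.927 with an estimated correlation. This group held the ARGLU1-rich library of sheep 255, without which the list had an adjusted p of 0.539, and without control sheep 132 it had 0.223.

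In subcutaneous fat the elastin gene ELN had the smallest p: it was at 96.1 ± 23.5 CPM in control and 18.4 ± 6.75 CPM in testosterone sheep, a log2 fold change of -2.36 (SE 0.29, edgeR adjusted p = 0.0562) that did not pass. Next came MEDAG, a gene of adipocyte differentiation, at -1.4 (SE 0.25), RHOJ at 1.6 (SE 0.31), the chemokine receptor ACKR3 at -1.06, SDR42E1 at 1.21, TRPM2 at 0.97, OTOGL at 2.34, SAMSN1 at 1.41, THNSL2 at -1.34 and CSMD2 at 2.92, all at an adjusted p of 0.903. ADIPOQ was at -0.14 (SE 0.35). By edgeR 0 of 12166 genes passed, 622 had an unadjusted p under 0.05 (5% of the genes tested is 608), and DESeq2 called 12, ELN among them. Of the fits without 1 sheep, ELN passed only in the one without testosterone sheep 185, and its edgeR adjusted p was up to 0.391 (without 233).

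As lists in subcutaneous fat, the T and NK cell list tested as higher, with 6 of 6 members positive, a median of 1.39, IL7R at 1.4 and CD3E at 1.48 (1 adjusted over the list alone; camera adjusted p = 1.55e-04, and adjusted p = 0.756 with an estimated correlation). The smooth muscle list tested as higher, with 9 of 10 positive, a median of 0.52 and LMOD1 at 2.45 (0 adjusted over the list alone; adjusted p = 0.0496, and adjusted p = 0.756 with an estimated correlation). The immediate early list tested as lower, with 4 of 19 positive, a median of -0.32 and FOSL2 at -0.85 (0 adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.756 with an estimated correlation). The extracellular matrix list tested as lower, with 12 of 31 positive, a median of -0.11 and BGN at -0.77 (1, ELN, adjusted over the list alone; adjusted p = 0.0496, and adjusted p = 0.805 with an estimated correlation). No member passed over all genes, and the group held the ARGLU1-rich library of sheep 48. Each call was lost without some sheep, with adjusted p of 0.0809 (without 233) for T and NK cells, up to 0.262 (without 233) for smooth muscle, up to 0.223 (without 185) for immediate early and up to 0.313 (without 255) for matrix genes.

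In perirenal fat no single gene passed, and the lists of smooth muscle and fibroblast genes passed as groups by camera with the preset correlation, not with an estimated one. Of 12 smooth muscle genes 11 were negative, with a median of -1.48, LMOD1 at -1.78 (SE 0.45) and desmin (DES) at -2.37 (SE 0.70). The list tested as lower (0 passed over all genes, 6 adjusted over the list alone; camera adjusted p = 4.42e-08, and adjusted p = 0.771 with an estimated correlation). Of 18 fibroblast genes 17 were positive, with a median of 0.58, GSN at 0.59 and PI16, a marker of adventitial progenitors, at 2.20 (SE 0.71). The list tested as higher (0 adjusted over the list alone; adjusted p = 5.81e-05, and adjusted p = 0.771 with an estimated correlation). The immediate early list tested as lower, with 17 of 19 negative, IER2 at -0.83 and CCN1 at -1.44 (1 adjusted over the list alone; adjusted p = 5.81e-05, and adjusted p = 0.771 with an estimated correlation). These 3 lists passed without each sheep in turn, at adjusted p of at most 4.12e-05, 0.00534 and 0.0407.

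Further perirenal lists passed less firmly. The lipogenic list tested as higher (15 of 21 positive, MLXIPL at 0.59, ELOVL6 at 1.32; adjusted p = 0.0458, and adjusted p = 0.825 with an estimated correlation) and the lipolysis list as lower (10 of 15 negative, ADRB3 at -0.84; adjusted p = 0.0312, and adjusted p = 0.825 with an estimated correlation). The interferon response list tested as lower (15 of 16 negative, ISG15 at -2.05; adjusted p = 0.0147, and adjusted p = 0.825 with an estimated correlation), and the positional list as higher (21 of 31 positive, HOXA9 at 0.50; adjusted p = 0.0458, and adjusted p = 0.771 with an estimated correlation). In these 4 lists 0 members passed, over all genes or adjusted over the list alone, and leaving out 1 sheep gave adjusted p of up to 0.788 (without 233), 0.254 (without 131), 0.999 (without 132) and 0.290 (without 132). Of single genes, those with the smallest p were P2RY14 at 1.00, BAIAP2L1 at -1.03, RHOJ at 1.27 (SE 0.26), TRIQK at 1.20, IER2 at -0.83, CD3EAP at -0.84, TCF15 at -0.99, the actin regulator DSTN at -0.70, MALL at -0.82 and TMEM72 at -3.87 (-7.21 without sheep 48), all at an edgeR adjusted p of 0.878. ADIPOQ was at 0.17 (SE 0.40). By edgeR 0 of 12872 genes passed, 691 had an unadjusted p under 0.05 (5% of the genes tested is 644), and DESeq2 called 9.

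In epicardial fat no single gene passed, and 3 lists passed as groups by camera with the preset correlation, not with an estimated one. Of 17 fibroblast genes 13 were negative, with DPT at -0.77 (SE 0.22) and COL3A1 at -0.64 (SE 0.19), from 1227 ± 116 to 764 ± 172 CPM, and of 31 matrix genes 20 were negative, with COL1A2 at -0.63. Both tested as lower as lists (camera adjusted p = 0.0144 and 0.0352, and adjusted p = 0.834 for both with an estimated correlation). Interferon response genes also tested as lower, with 14 of 17 negative, IFIT1 at -1.14 and IFI44 at -0.66 (adjusted p = 0.0243, and adjusted p = 0.834 with an estimated correlation). In these 3 lists 0 members passed, over all genes or adjusted over the list alone. The single genes with the smallest p were RBMX2 at 0.95, SERPINF1, the gene of the antiangiogenic factor PEDF, at -1.29 (SE 0.23) and the cytokinesis gene ANLN at -1.84 (edgeR adjusted p = 0.565). Next came PURA at 0.83, MYO6 at 1.20, ZMAT1 at 1.73, RHOJ at 1.36 (SE 0.29), SEMA6A at 0.71, TLN2 at 0.72 and ADA at -1.02 (adjusted p = 0.697). With ARGLU1 as a covariate MYO6 was at 0.50, ZMAT1 at 0.88 and RHOJ at 0.64. By edgeR 0 of 12793 genes passed, 723 had an unadjusted p under 0.05 (5% of the genes tested is 640), and DESeq2 called 11. ARGLU1 was at 1462 to 4743 CPM in testosterone and 679 to 1510 CPM in control epicardial libraries, LUC7L3 at 1570 to 4099 and 1154 to 1596 CPM, and the testosterone library of sheep 255 had a fitted perirenal share of 45.0%. The heart muscle content ran from 135 to 32815 CPM, and the fibroblast list had an adjusted p of 0.0817 without sheep 255, the matrix list up to 0.260 (without 201) and the interferon list up to 0.556 (without 132).

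Over all depots, 1 gene passed: RHOJ, a gene expressed in endothelial cells and adipocyte precursors, rose in testosterone sheep by 1.38 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0256). It was higher in 4 of 4 testosterone sheep in every depot. Its level was 10.8 ± 2.68 CPM in control and 50.1 ± 42.5 CPM in testosterone visceral fat, and 13.2 ± 3.29 and 40.5 ± 15.8 CPM in subcutaneous fat. It was 12.8 ± 4.30 and 30.8 ± 6.55 CPM in perirenal, and 28.1 ± 6.71 and 69.8 ± 23.8 CPM in epicardial fat (SD, n = 4). DESeq2 called RHOJ in each depot. Its effect in 1 depot minus the mean of the other 3 was 0.69 (SE 0.45) in visceral, -0.05 (SE 0.46) in subcutaneous, -0.43 (SE 0.45) in perirenal and -0.21 (SE 0.44) in epicardial fat, none of which passed. Leaving out 1 sheep gave log2 fold changes from 1.29 (without 255) to 1.44 (without 233), and the call was lost without 48, 98, 131, 132, 201 or 255. With ARGLU1 as a covariate the fold was 1.11 (SE 0.14, adjusted p = 0.213), and that fit called 1 other gene, THNSL2.

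**Figure D4:**
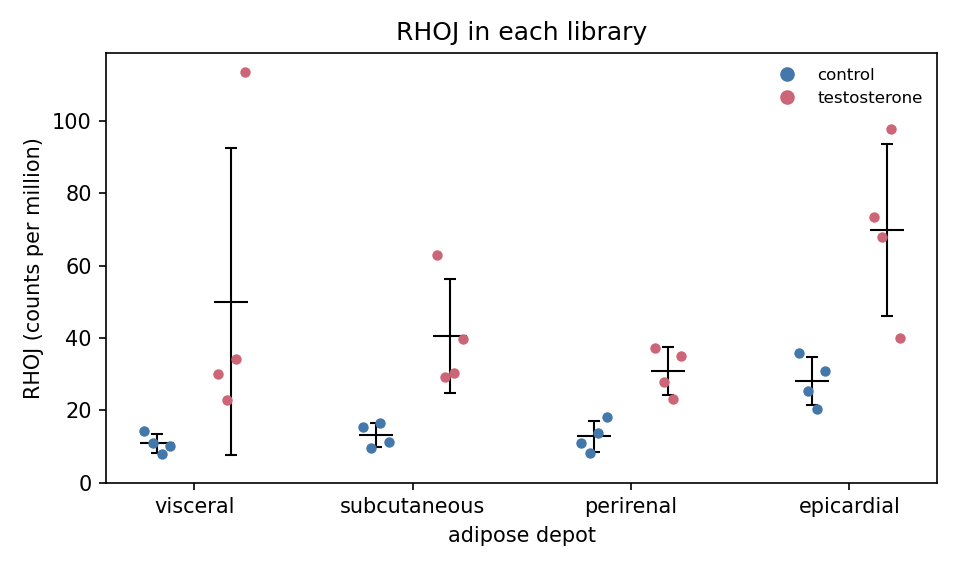
RHOJ in CPM, with 1 point per library and the mean ± SD of 4 libraries in black, by depot and treatment. Testosterone libraries lie above control libraries in each depot, and the visceral library of sheep 255, at 113.5 CPM, is the highest.

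After RHOJ came 4 genes at an edgeR adjusted p under 0.10, which did not pass. TCEAL2, at 0.0774 ± 0.0903 CPM in control and 3.41 ± 2.13 CPM in testosterone visceral fat, had no overlap between groups in any depot and an adjusted p of 0.0687. The TCEAL2 gap rested on few reads: up to 3 counts in subcutaneous controls against 4 in testosterone sheep 185, and up to 2 in epicardial controls against 5 in sheep 48. RHOJ and TCEAL2 were the 2 of 15817 genes without overlap in all 4 depots, where chance gives 2.86% per depot. The same sheep stand in all depots, so these chances cannot be multiplied, and 6 of 35 splits of the sheep gave as many such genes (highest other 3). The synaptic gene LRRTM1 was at 1.15 (SE 0.15, adjusted p = 0.0687) and was highest in the 2 ARGLU1-rich libraries, without which it was at 0.61 in the limma-voom fit. Next came the aldolase DERA at 2.30 (SE 0.32, adjusted p = 0.0776) and ANKEF1 at -0.98 (SE 0.13, adjusted p = 0.0776). PLPP1 at -0.70, MTFMT at 0.68, REEP1 at -0.79, GNG8 at 1.55 (0.98 without those libraries in the limma-voom fit) and LMTK3 at 1.61 had adjusted p from 0.212 to 0.488. ESR1 at 0.38 (SE 0.25), PPARG at -0.04 (SE 0.11), ADIPOQ at -0.14 (SE 0.23) and LEP at 0.24 (SE 0.55) did not pass. Of 15301 genes tested by edgeR, 1041 had an unadjusted p under 0.05 (5% of the genes tested is 765), and DESeq2 called 61. The immediate early list tested as lower, with 18 of 21 negative, IER2 at -0.45 and CCN1 at -0.93 (0 adjusted over the list alone; camera adjusted p = 0.00326, and adjusted p = 0.986 with an estimated correlation), a call lost without sheep 131 (adjusted p = 0.273) or 185 (0.0737).

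The last comparison asks whether the effect of testosterone differed between depots. PCOLCE2, which enhances procollagen processing, passed edgeR's test of this in perirenal fat. It stood at 128 ± 33.7 CPM in control and 314 ± 139 CPM in testosterone sheep there, with sheep 48, at 113.9 CPM, inside the control range (99.62 to 176.5). Its levels were 299 ± 63.7 and 149 ± 73.2 CPM in visceral, 119 ± 28.4 and 66.7 ± 24.3 CPM in subcutaneous and 253 ± 75.9 and 187 ± 51.6 CPM in epicardial fat. Its perirenal effect minus the mean of the others was 1.99 (SE 0.33, edgeR adjusted p = 0.0329). The unnamed locus LOC105603774 passed the epicardial contrast (-9.57, SE 1.17, adjusted p = 0.00247) and the joint test (adjusted p = 0.0153). The size of that contrast and its SE are not determined, since the gene had no count in perirenal controls, and the contrast ran from -13.36 to -6.35 over the alternatives. It was seen in epicardial fat at 127 and 31.8 CPM in control sheep 98 and 131, the controls with the most heart muscle transcripts, at 0 in the other 2 controls and at no more than 0.591 CPM in testosterone sheep, with no count in sheep 48 and 233, whose epicardial libraries held 32815 and 4980 CPM of heart muscle transcripts. In the joint test the next genes were PCOLCE2 (adjusted p = 0.156) and RGCC, ANLN, KLF9, HOXB2, ZNF787, NBDY, HSPA12B, GBP6 and MMP16 (0.932). The PCOLCE2 call was kept in 1 of the 8 fits without a sheep (without 48), and the joint call was lost without 48, 98, 131 or 233. The PCOLCE2 call was also lost without the ARGLU1-rich libraries, without the epicardial library of sheep 255 and with no sheep block.

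Of 14225 genes tested by edgeR, the joint test called 1 (656 at an unadjusted p under 0.05, and 10 by DESeq2), the visceral contrast 0 (895, and 3 by DESeq2), the subcutaneous 0 (459, and 2), the perirenal 1 (787, and 5) and the epicardial 1 (629, and 0). Across genes, the effects of testosterone in 2 depots were correlated, with r of 0.542 (Spearman 0.473) for visceral and subcutaneous, 0.370 (0.317) for visceral and epicardial, 0.425 (0.378) for subcutaneous and epicardial, and 0.297 (0.248) for visceral and perirenal fat. It was 0.218 (0.161) for subcutaneous and perirenal and 0.129 (0.0849) for perirenal and epicardial fat. Genes are not independent replicates, and the same sheep stand in both depots. Of the 35 splits of the sheep, 6, 1, 2, 19, 25 and 19 gave an r as large, with highest other values of 0.627, 0.348, 0.425, 0.483, 0.421 and 0.259.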

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

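The tests of ARGLU1, heart muscle, depot shares and neighbouring genes in this part, and the splits or permutations for lists, for genes without overlap and for unadjusted p, were chosen after the results were seen; those for counts of genes at the FDR were planned. Several measures were tested with Dixon's ratio in each combination of depot and treatment. Of these 64 tests, each on 4 libraries, 7 lay above the 95% critical value. Chance gives about 1 in 20, or 3.2, for independent measures chosen beforehand. The measures share libraries, and ARGLU1 and LUC7L3 were chosen after their values were seen, so setting 7 against 3.2 decides nothing. The libraries far from others of their group were the epicardial library of testosterone sheep 48 in cardiac muscle genes (ratio 0.852), the visceral library of testosterone sheep 255 in ARGLU1 (0.927), LUC7L3 (0.876) and RHOJ (0.874). Others were the subcutaneous library of testosterone sheep 48 in ARGLU1 (0.961) and LUC7L3 (0.905), and the epicardial library of testosterone sheep 255 in HOXC6 (0.977). A difference of the testosterone effect between depots was seen by the interaction test for PCOLCE2, at 1.99 in perirenal fat minus the mean of the others, and for LOC105603774, at -9.57 in epicardial fat and with an adjusted p of 0.0153 in edgeR's joint test.

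RHOJ was higher in testosterone sheep in each depot. A first explanation is chance: 5 of the 35 splits of the 8 sheep call at least as many genes over depots (1, and 1 in the highest other split). Likewise 6 of 35 have as many genes without overlap in all 4 depots (2, highest other 3), so chance is not excluded by either count. A second is the 2 libraries rich in ARGLU1: without them the log2 fold change was 1.33 (SE 0.17, limma-voom adjusted p = 1.04e-04, sheep as random effect), which excludes them as the whole cause. A further one is a graded difference in library quality: with ARGLU1 as covariate the fold over depots went from 1.38 (SE 0.14) to 1.11 (SE 0.14) and the call ended (edgeR adjusted p = 0.213), while it went from 2.26 to 1.15 in visceral, 1.6 to 1.21 in subcutaneous, 1.27 to 1.2 in perirenal and 1.36 to 0.64 in epicardial fat, so quality stays open as a part of the effect. Of the 20 genes nearest to RHOJ, 2 had an unadjusted p under 0.05 (SYNE2 at 0.53 and LOC105607030 at 0.77), and an effect of testosterone on RHOJ remains possible.

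The epicardial library of testosterone sheep 255 held trunk HOX genes, and perirenal fat RNA mixed into the sample could account for this: the fitted perirenal share of the library was 45.0%, against at most 3.79% in the other 7 epicardial libraries. The fit allowed only the 4 depot profiles and used genes that differ between depots, such as HOXC6, so it is no independent evidence. Not every gene followed a 45.0% share. PCOLCE2, at 129.6 CPM, was at 37.5% of the perirenal library of that sheep and below the other epicardial libraries (153.5 to 337.8). WT1 was at 40.5%, and the 14 genes near 0 in control epicardial fat had quartiles of 38.8% and 59.5%. Shares of other depots were also fitted in the perirenal library of control sheep 98 (34.8% visceral) and the visceral library of testosterone sheep 255 (27.4% subcutaneous and 19.8% epicardial), and were not tested further. A mislabelled perirenal sample is excluded, since genes specific to epicardial fat stood at 50.3% of their control level (14.0% in the perirenal library of that sheep). An effect of testosterone shared by the group is excluded, since genes near 0 in control epicardial fat stood at 43.9% of the own perirenal level in sheep 255 and at most 1.5% in the other 3 testosterone sheep. A trait of this 1 sheep was not tested.

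Genes of epicardial fat could come from heart muscle taken with the samples, whose transcripts reached 25348 CPM in control sheep 98. As the whole cause this is excluded: apart from muscle markers, the lowest share of genes with the same sign over the 7 sheep other than 255 was 81.0% for the higher and 85.9% for the lower genes, both in sheep 48, and control sheep 132, with 148 CPM of cardiac transcripts, had 88.8% and 93.4%. Sheep 255, with 135 CPM, had 62.8% and 47.9%, the direction heart muscle predicts; it was set aside after this value was seen, because its library held perirenal genes. How much of a single gene's fold comes from muscle was not tested.

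Chance was also weighed for the counts by regrouping. Within depots the real count of genes was 0, which 35 of 35 splits reach by construction, so this says nothing about chance. There the highest other counts were 1 (visceral), 1 (subcutaneous), 278 (perirenal) and 1 (epicardial). The split with 278 genes, sheep 48, 98, 201 and 255 against the rest, points to a structure of the samples, whose cause was not tested. At an unadjusted p under 0.05, 5 of 35 splits reached the visceral 1212 (highest other 1508), 9 the subcutaneous 622 (1122), 11 the perirenal 691 (2376), 9 the epicardial 723 (2020) and 4 the over-depot 1041 genes (1751), so chance is not excluded for these counts. For gene lists, 35 visceral (real 1, highest other 18), 21 subcutaneous (4, 10), 21 perirenal (7, 12), 33 epicardial (3, 17) and 35 over-depot splits (1, 14) did as well, so chance is not excluded for any count of lists between treatments. In the interaction, 6 splits of the joint test (real 1, highest other 96), 5 of the perirenal (1, 3) and 6 of the epicardial contrast (1, 220) did as well, so chance is not excluded there. For the visceral and subcutaneous contrasts (real 0, highest other 0) 35 of 35 do so by construction.

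For depot genes in control sheep, 1 of 100 permutations of the depot labels within sheep, the real one, reached the count in each depot, and the highest others were 38 (visceral), 163 (subcutaneous), 1639 (perirenal) and 24 (epicardial). This is the smallest share the test can give, and labels without any depot difference are excluded at that level. The perirenal count of 1841 lay close to its highest other, so the test says little about its size. In testosterone sheep 3, 1, 2 and 3 of 100 permutations reached the count, with highest others of 1160, 7, 160 and 1296. What these permutations hold was not tested, and a permuted label can coincide with 1 real depot in several sheep. For lists in control sheep, 29 permutations reached the visceral count (9, highest other 16), 3 the subcutaneous (15, 16), 68 the perirenal (6, 17) and 19 the epicardial (11, 16). The subcutaneous count was the least often reached, but a permutation exceeded it. This test was chosen after the results were seen and run on several counts, so chance is not excluded for any of them.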

How the results depend on the processing

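Fits without the ARGLU1-rich or mixed-looking libraries, and those with ARGLU1 or cardiac marker levels as covariate, were tests chosen after the data were seen. Where a value below differs from the report, the cause was not tested, except that fewer sheep or a looser FDR change the counts by construction. The lowest depth was 784135 counts, in the subcutaneous library of sheep 48, and how much depth limits each comparison was not tested. With the real depths and spreads, of simulated 2-fold changes 10% in visceral, 12% in subcutaneous, 29% in perirenal and 24% in epicardial fat were recovered.

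Genes for testosterone, against 0 in each depot: DESeq2 called 21 in visceral, 12 in subcutaneous, 9 in perirenal and 11 in epicardial fat, 1 fit of all libraries 3 in visceral, and in subcutaneous fat an FDR of 0.10, no filter and 1 surrogate variable called 1 each, with 0 to 1 leaving out 1 sheep (1 without 185). Over depots, against 1: FDR of 0.10 gave 5, no filter 5, DESeq2 61, the random effect of sheep 26, the same without 2 libraries 15, without the epicardial library of sheep 255 33, without all 3 29, and leaving out 1 sheep 0 to 4 (without 185). With ARGLU1 as covariate the count stayed at 1, but the gene was THNSL2 in place of RHOJ.

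Interaction, joint, against 1: stricter filter 0, DESeq2 10, voom weights 0, no block 0, without 2 libraries 0, without 3 libraries 0, leaving out 1 sheep 0 to 1. Visceral, against 0: DESeq2 3. Subcutaneous, against 0: DESeq2 2, without 3 libraries 1. Perirenal, against 1: DESeq2 5, voom weights 7, no block 0, without 2 libraries 0, without the epicardial library 0, without 3 libraries 0, leaving out 1 sheep 0 to 2 (without 48). Epicardial, against 1: stricter filter 0, DESeq2 0, voom weights 0, no block 0, leaving out 1 sheep 0 to 1.

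Depot genes in control sheep: visceral 766 became 1367 at an FDR of 0.10, 1175 with voom weights, 273 with no block and 202 (without 131) to 461 (without 132) leaving out 1 sheep; subcutaneous 3075 became 1743 (without 132) to 2286 (without 98); perirenal 1841 became 2867 at an FDR of 0.10, 1054 with no block and 656 (without 98) to 1584 (without 132). In testosterone sheep, visceral 12 became 44 at an FDR of 0.10, 26 with no filter, 156 by DESeq2, 124 with voom weights, 26 without 2 libraries, 22 without the epicardial library, 67 without 3 and 3 (without 233) to 35 (without 255). Subcutaneous 341 became 671 at an FDR of 0.10, 840 by DESeq2, 853 with voom weights, 207 with no block and 71 (without 185) to 384 (without 255). Perirenal 75 became 239 at an FDR of 0.10, 859 by DESeq2, 1415 with voom weights, 25 with no block, 235 without 2 libraries, 339 without the epicardial library, 825 without 3 and 5 (without 185) to 100 (without 255). Epicardial 598 became 1070 at an FDR of 0.10, 1204 by DESeq2, 1568 with voom weights, 2199 without 2 libraries, 1069 without the epicardial library, 2651 without 3 and 101 (without 233) to 1578 (without 255).

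Lists for testosterone with an estimated correlation: 0 in visceral, subcutaneous, perirenal and epicardial fat and 0 over depots. By fry: 0 in visceral, 1 in subcutaneous, 0 in perirenal and 0 in epicardial fat. Leaving out 1 sheep: visceral 0 (without 132) to 5 (185), subcutaneous 2 (233) to 4, perirenal 4 (98) to 8 (233), epicardial 2 (201) to 9 (98), over depots 0 (185) to 3 (48). In control depots with an estimated correlation: 0 visceral, 2 subcutaneous, 1 perirenal and 0 epicardial; by fry 3 visceral and 18 epicardial; leaving out 1 sheep, visceral 1 (131) to 10 (201). With no filter, r between effects was 0.213 (visceral and subcutaneous), 0.144 (visceral and perirenal), 0.144 (visceral and epicardial), 0.102 (subcutaneous and perirenal), 0.126 (subcutaneous and epicardial) and 0.068 (perirenal and epicardial).

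Of the RHOJ contrasts between depots, none of which passed, 3 turned direction. Visceral 0.69 ran from -0.034 (without 255) to 0.97 (without 48). Subcutaneous -0.05 was 0.055 with voom weights and 0.058 without 2 libraries, and ran from -0.29 (without 48) to 0.18 (without 132). Epicardial -0.21 was 0.18 without the epicardial library of sheep 255, 0.26 without 3 libraries, and ran from -0.54 (without 233) to 0.21 (without 255). Among the 104 values of single genes run under the alternatives (a gene counts once per comparison), no other turned direction; the further genes named in the report were not run. With DESeq2 size factors 104 of 104 kept their direction and their side of the threshold, as did all 102 that could be run with the stricter filter, 102 of 104 with voom weights and 99 of 104 with no filter. By DESeq2's test 63 did, 40 came past the threshold and 1 was lost.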

Other observations

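ADIPOQ, the gene of the adipocyte hormone adiponectin, differed between depots of control sheep. It was at 14485 ± 4585 CPM in visceral and 5805 ± 1938 CPM in epicardial fat, with log2 fold changes of 0.71 (SE 0.16, edgeR adjusted p = 0.0159) and -1.04 (SE 0.18, adjusted p = 3.73e-04). Leptin (LEP), PPARG and the estrogen receptor gene ESR1, at 287 to 434, 285 to 367 and 36.2 to 57.6 CPM, passed in no depot.

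The test in this paragraph was chosen after the result was seen. As a hypothesis, the correlation of testosterone effects between visceral and epicardial fat may reflect differences in library quality between the 2 groups of sheep. On log2 CPM of 12511 genes (limma), r was 0.355, and 3 of 35 splits were as large (highest other 0.361). With ARGLU1 as a covariate r was 0.0540, and 35 of 35 splits were as large (highest other 0.343). Since at least 5% of splits were as large without the covariate too, this test decides nothing, and the hypothesis stays open. Of the other pairs, r went from 0.389 to 0.0895 for subcutaneous and epicardial, 0.519 to 0.247 for visceral and subcutaneous and 0.173 to 0.106 for perirenal and epicardial fat. It did not fall for visceral and perirenal (0.295 to 0.315) or subcutaneous and perirenal fat (0.203 to 0.237).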
